A study of Homo sapiens with 27 samples.

How the data were processed

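Messenger RNA was sequenced from 9 established human cell lines with 3 libraries per line, 27 libraries in all. Per the labels' protocols, RNA was extracted with a column kit, met a stated integrity threshold, and was made into strand-specific libraries after poly-A selection. The submitters' processing notes name CASAVA 1.8, kallisto 0.43.1 and the GRCh 38 genome build, without saying how each was used. The annotation release behind the transcript index, and any strand, bias or bootstrap setting, are not given in the sources used here. The series design text describes parallel proteomics, which was not analysed here.

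Each library had 1 deposited table. Per the file headers, the authors' tables hold an estimated count, a TPM (an abundance scaled to transcript length and library total) and an effective length for each transcript. The deposited estimated counts are reads assigned to transcripts in proportion and need not be whole. The deposited TPM values are scaled by the authors' software to effective transcript length and to the library total, so that 1 abundant transcript class lowers the TPM of all others. Each table listed the same 176241 transcripts, of which 159887 matched a transcript of GENCODE release 29 by identifier without version. The remaining 16354 transcripts (9.28%) were left out of the gene values. The matched transcripts belonged to 34584 genes, 19675 of them protein coding. Estimated counts were summed to genes and rounded to whole numbers, and TPM values were summed to genes. Coordinates are those of GENCODE 29 on GRCh 38.

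Samples were grouped by the cell line label. Libraries of a line are numbered 1 to 3. The numbers after P in the sample titles have no stated meaning and were used only in alternatives. Libraries held between 15597117 and 32583547 estimated counts, with a median of 26090811. Replicates were compared with chi-square statistics over genes. The median over genes was divided by the median of the chi-square distribution with 1 degree of freedom. The lowest such ratio within a line was 5.44, so no library was treated as a second copy of another.

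Gene counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood, robust, 1 coefficient per line, TMM factors, genes kept by filterByExpr). All 27 libraries entered 1 fit, because each line has only 3 libraries to estimate its spread. The fit held 17220 genes, 16086 of them protein coding, with a biological coefficient of variation of 24.2%. An F test over the lines used a Benjamini-Hochberg false discovery rate of 0.05. A gene counted as line-enriched when it passed 8 one-sided tests, 1 against each other line, at a false discovery rate of 0.05 on the largest of the 8 p-values, and lay at least 4-fold above the next highest line. SK-Mel 28 was tested against SK-Mel 24, and the mean of both against the mean of the other 7 line means. Each line was also tested against the mean of the other 8. These contrasts asked for an adjusted p under 0.05 and an absolute log2 fold change of at least 1. The contrast with the mean of the other lines averages on a log scale, and it cannot call a gene lower in a line when another line is at 0 counts. Counts of lower list members can therefore miss genes. A line at 0 counts also pulls this mean down, so a gene can be called higher at a low level, or without being highest in that line. In HepG2, for example, APOA4 was called higher at 0.86 ± 0.64 TPM (log2 fold change 7.66).

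A total of 40 gene lists were fixed before the data were examined. They covered the cell types named by the tissue labels, other cell types, signalling and metabolic programmes, and gene clusters. The BAGE, H19 and MEG3 entries had no counterpart among the matched genes. Lists were tested with camera in limma 3.58.1 on log2 CPM computed from the same counts, with a preset correlation of 0.01, over 11 contrasts (440 tests adjusted together). The same tests were run with a correlation estimated from the data, and with fry, which asks only whether the genes of a list move in 1 direction. Counts of list members are given over all tested genes. Where the count adjusted over the list alone differed, it is given beside it.

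The genes named were chosen by a rule set before the data were examined. The rule took the 8 protein-coding line-enriched genes with the largest margin in each line and the 12 with the largest change in each direction between the SK-Mel lines (mean TPM of at least 5 in the higher line). It also took the 10 with the largest margin of both SK-Mel lines over the others, the list members with the largest change, and members of the telomere, 9p21 and growth receptor lists. Some of the genes the rule took are not reported here. Genes named outside the rule are marked as chosen after their values were seen. A fold against a line with 0 counts in all its libraries is a lower bound. It was computed against 3 counts over the 3 libraries of that line, and it covers counting error only.

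The dominant transcript of a gene was the one with the largest share of the gene's TPM in all 3 libraries of a line. A switch between a pair of lines required different dominant transcripts, a share difference of at least 0.2 for both, and at least 100 estimated counts in every library of both lines. Switches were counted by these thresholds without a test, as set before the data were examined, so a switch has no p-value.

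The tests were checked on simulated counts with known changes, drawn for 16290 genes. Between the SK-Mel lines, 32% of simulated 2-fold, 90% of 4-fold and 100% of 8-fold and 16-fold changes were recovered, with 4 false calls. For SK-Mel 28 enrichment, none of the 2-fold, 10% of 4-fold, 98% of 8-fold and 100% of 16-fold changes were recovered, with 0 false calls. In this simulation all lines had the same gene means, apart from 200 genes changed in SK-Mel 28. Spread between libraries depended only on gene level and was alike in all lines. The false-call counts therefore do not cover lines that differ in most genes, or the larger spread between the HepG2 libraries. In a simulation over 10108 genes, 190 of 200 planted transcript switches were recovered, and 19 other genes were called in 1 or more of 36 pairs of lines. Switches were planted only in genes with at least 300 counts and a share lead of at least 0.3. Transcript counts were drawn directly, so errors in assigning reads to similar transcripts are not covered. Alternatives covered size factors, the low-count filter, DESeq2 1.42.0, transcript length offsets, covariates, single libraries left out, and the settings of each list and transcript rule. Added after the data were seen were fits without HepG2, without mitochondrial genes, and without genes of the major histocompatibility complex (MHC) region. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.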

Results

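The transcriptomes of 9 human cell lines were measured by poly-A RNA sequencing, with 3 libraries per line. SK-Mel 24 and SK-Mel 28 are melanoma lines and the only pair with a shared tissue label (skin). The other lines were U2-OS (osteosarcoma, labelled bone), A549 (lung adenocarcinoma), U251 (glioblastoma, labelled brain), Caco2 (colorectal adenocarcinoma), HepG2 (liver tumour), BJ (dermal fibroblasts, labelled epithelial) and RT4 (a bladder tumour line, labelled kidney). The series design names the 3 libraries of a line biological replicates. How separate their cultures were is not stated, so p-values measure only the spread between these libraries. Growth media differed between lines, so line and medium cannot be separated.

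Libraries held 15597117 to 32583547 estimated counts. Gene levels of libraries from the same line correlated with a Spearman coefficient of 0.93 to 0.951 (27 pairs, across genes). Between lines the range was 0.814 to 0.904 (324 pairs). Genes are not independent replicates, so these are descriptions. The pair of lines with the highest mean correlation was SK-Mel 24 and SK-Mel 28 (0.902), followed by SK-Mel 24 and U251 (0.898). HepG2 differed most from U2-OS (0.821).

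Mitochondrial transcripts took 71.1%, 33.8% and 32.6% of the counts of the HepG2 libraries, against 0.93% to 5.72% in the other 24 libraries. Protein-coding genes at 1 TPM or more numbered 8055, 9880 and 10002 in HepG2 and 11367 to 12828 elsewhere. The mitochondrial share lowers the TPM of all other genes in HepG2. Fewer genes there can reach 1 TPM for that reason alone, and HepG2 TPM values understate other genes.

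**Figure D1:**
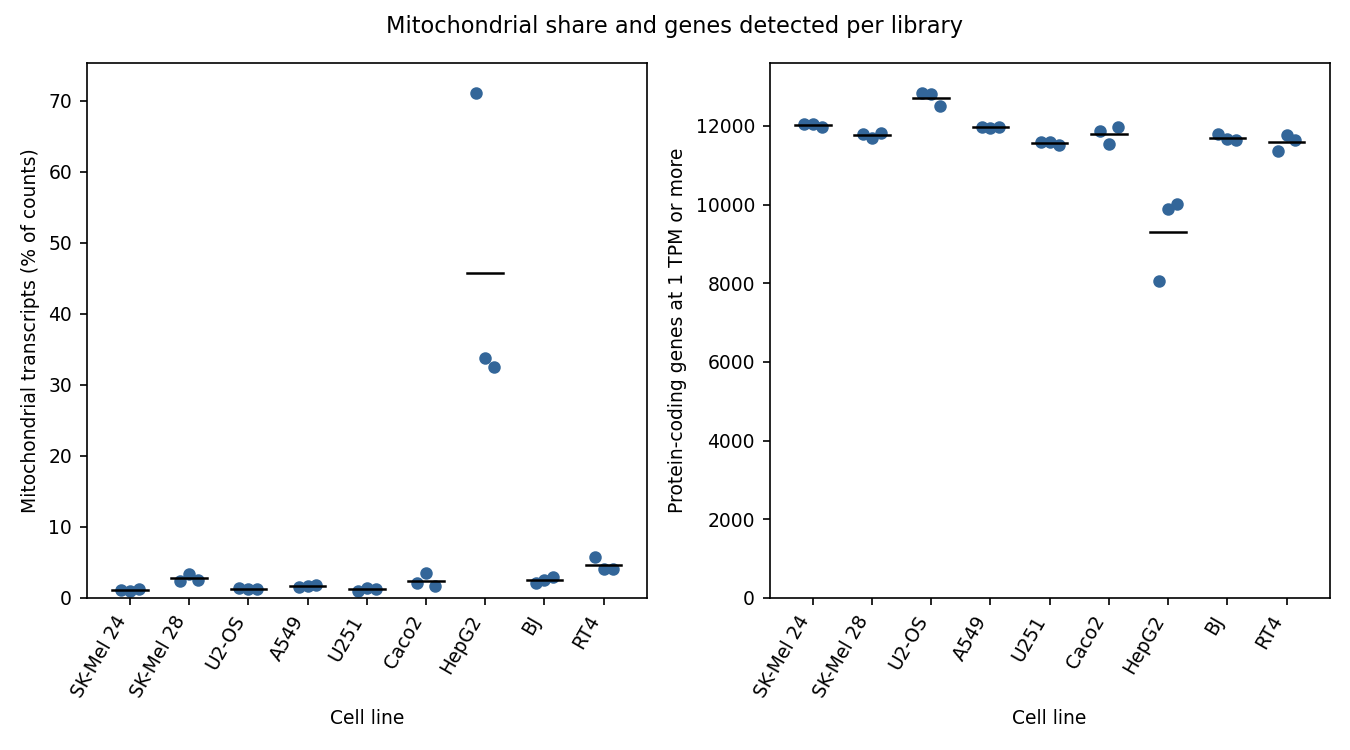
Share of estimated counts on mitochondrial transcripts (left, percent) and number of protein-coding genes at 1 TPM or more (right) in each library. Points are libraries and bars are means of the 3 libraries of a line; the HepG2 libraries lie at 32.6% or more and at 10002 genes or fewer.

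The first comparison asked which genes differed among the 9 lines. Nearly every expressed gene did: 16922 of 17220 tested genes (98.3%) passed the F test, and 298 did not. Among 11792 genes with a mean of at least 10 TPM in some line, the highest and lowest line means differed by 16-fold or more in 3902 (33.1%) and by less than 2-fold in 115. Pairs of lines differed in between 5319 genes (SK-Mel 24 and U251) and 10098 genes (U2-OS and HepG2).

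The second comparison asked which genes set 1 line apart from all others. A total of 2424 genes (2164 protein coding) were line-enriched, from 54 in U251 to 657 in HepG2. Among protein-coding genes the counts were 148 in SK-Mel 24, 189 in SK-Mel 28, 252 in U2-OS, 136 in A549, 50 in U251, 187 in Caco2, 580 in HepG2, 291 in BJ and 331 in RT4. For 275 of the HepG2 genes, the next highest line was Caco2. Without HepG2, an alternative chosen after the data were seen, Caco2 had 445 enriched genes of any type. The median log2 difference of all tested genes from the mean of the other lines was -0.17 in HepG2 and 0.13 in U2-OS, and list changes are read against it.

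**Figure D2:**
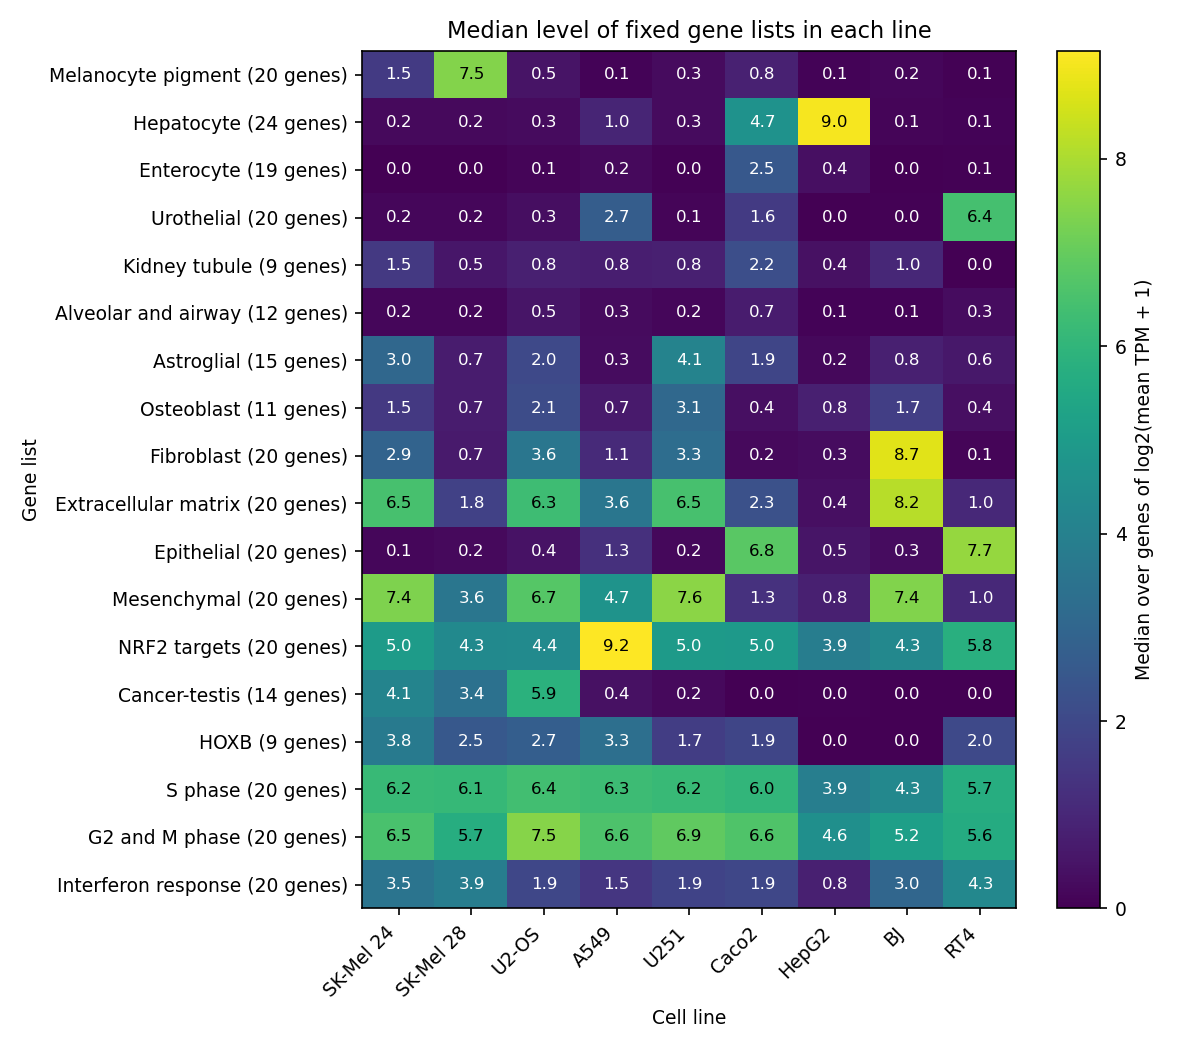
Median over the tested members of each gene list of log2(mean TPM + 1) in each line, with lists down the side and lines across. The melanocyte list peaks in SK-Mel 28, the hepatocyte list in HepG2, the urothelial list in RT4, the fibroblast list in BJ and the NRF2 target list in A549. HepG2 values are lowered by the mitochondrial share of its libraries.

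SK-Mel 28 had the expression of a pigmented melanocyte. All 20 members of the melanocyte list were higher than the mean of the other lines (camera adjusted p = 1.83e-16, and adjusted p = 0.00277 with an estimated correlation). PMEL, a structural protein of melanosomes (chromosome 12, 55954105 to 55973317), reached 8877 ± 2255 TPM (SD, n = 3), against 8.24 ± 3.6 in the next highest line by fitted level, Caco2. TYR, the rate-limiting enzyme of melanin synthesis, stood at 444 ± 89.3 TPM and DCT, a further melanin enzyme, at 427 ± 72.9. The melanosomal transporter SLC45A2 stood at 144 ± 13.9 TPM, and PLA1A, a phospholipase, at 531 ± 47.2.

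SK-Mel 24 divided the same list. The list was higher as a whole (11 of 20 up, and 3 down, or 1 down without replicate 1 or without replicate 2; camera adjusted p = 0.0406), with adjusted p = 0.396 with an estimated correlation. The call was also lost without SK-Mel 24 replicate 3 (adjusted p = 0.0676) and without HepG2 (0.0961). Neural crest members led the rise, namely S100B at 7822 ± 1439 TPM, SOX10 at 252 ± 30.8 and EDNRB at 66.3 ± 12.9. In this line 17 of 20 mesenchymal list members were higher (adjusted p = 0.0246 with an estimated correlation), among them NGFR (82.1 ± 20.5 TPM), TNC (446 ± 103) and ZEB2 (75.2 ± 10.3). All 8 tested members of the MHC class II list were higher (adjusted p = 0.00887 with an estimated correlation), and those in the MHC region are uncertain because their reads can be shared with other copies. The cancer-testis gene MAGEC2 (chromosome X, 142202345 to 142205290) was at 147 ± 13.6 TPM and at 0.07 ± 0.04 in U2-OS. FDCSP, at 210.6 ± 315 TPM, rested largely on 1 library, and its enrichment was lost with DESeq2 and without the low-count filter.

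HepG2 carried the hepatocyte programme at very high levels. A total of 23 of 24 tested members of the hepatocyte list were higher (adjusted p = 0.0317 with an estimated correlation) and the other, CYP2E1 (chosen after its value was seen), was at 0.03 ± 0.02 TPM. Albumin, ALB (chromosome 4, 73397114 to 73421412), was at 7110 ± 4482 TPM against 3.15 ± 2.66 in Caco2, and the apolipoprotein genes APOA1 and APOB were at 5198 ± 3511 and 187 ± 103. The libraries of this line also differed in mitochondrial share, at 71.1%, 33.8% and 32.6%. All 13 mitochondrial genes tested were higher (camera adjusted p = 3.91e-08), as were 13 of 24 ribosomal protein genes with 1 lower, but neither list passed with an estimated correlation (adjusted p = 0.315 with an estimated correlation for the first, and adjusted p = 0.51 with an estimated correlation for the second). Of 8 haematopoietic genes, 7 were higher (adjusted p = 0.0278 with an estimated correlation), led by LYZ, the lysozyme gene, at 571 ± 387 TPM and CD74 at 169 ± 73.8. By TPM the list was not highest in HepG2: its median log2(mean TPM + 1) was 1.33 in HepG2 and 2.24 in Caco2. CD74 was also higher by TPM in both SK-Mel lines than in HepG2. The mitochondrial share lowers the TPM of other genes in HepG2, so these TPM comparisons understate HepG2 and do not settle its rank. ITGB2 and HBA1 were at only 1.98 ± 1.14 and 1.13 ± 1.16 TPM in HepG2.

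Caco2 joined enterocyte, epithelial and liver-type genes. Of 19 enterocyte genes, 17 were higher (adjusted p = 0.000823 with an estimated correlation), with the intestinal regulator CDX2 at 56.6 ± 9.99 TPM and the brush border gene VIL1 at 333 ± 113. ALPI, intestinal alkaline phosphatase, was at 10.6 ± 3.82 TPM and BTNL8 (chromosome 5, 180899077 to 180950906) at 17.4 ± 0.608. Of the 24 hepatocyte genes, 21 were higher and 1 lower (camera adjusted p = 1.22e-09), with adjusted p = 0.091 with an estimated correlation. FABP1, which both lists hold, was at 372 ± 76 TPM, and VTN at 724 ± 238. The enterocyte list was also higher in HepG2, with 12 of 19 members up (camera adjusted p = 0.0264), and adjusted p = 0.0799 with an estimated correlation.

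RT4, labelled kidney, had a urothelial profile. All 20 urothelial genes were higher (camera adjusted p = 1.47e-15, and adjusted p = 0.00139 with an estimated correlation), including the uroplakins UPK1B at 129 ± 28.5 TPM and UPK3B at 47.2 ± 14 and the cofactor VGLL1 at 349 ± 45.1. No kidney tubule gene was higher and 4 of 9 were lower, or 7 with DESeq2 (camera adjusted p = 0.0287), with adjusted p = 0.127 with an estimated correlation. CRYAB was at 0.54 ± 0.13 TPM and CUBN, a tubular endocytic receptor, at 0.01 ± 0.01. Of the 20 epithelial genes, 19 were higher (adjusted p = 0.013 with an estimated correlation). CYP4B1 (chromosome 1, 46757838 to 46819413) was at 416 ± 85.5 TPM and the connexin gene GJB6 at 152 ± 34.2, both far above any other line. Of the 20 interferon response genes, 15 were higher (camera adjusted p = 8.18e-05), with adjusted p = 0.338 with an estimated correlation.

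BJ, labelled epithelial, had a fibroblast profile. All 20 fibroblast genes were higher (camera adjusted p = 6.24e-16, and adjusted p = 0.00902 with an estimated correlation), with the collagen genes COL1A2 at 7215 ± 3025 TPM and COL1A1 at 2877 ± 1303, and the matrix genes LUM at 1772 ± 775 and DCN at 544 ± 194. Of 20 extracellular matrix genes, 19 were higher (adjusted p = 0.0175 with an estimated correlation), and 19 of 20 mesenchymal genes were higher with 1 lower (adjusted p = 0.023 with an estimated correlation). In the epithelial list 4 genes were higher and 8 lower (camera adjusted p = 0.00478), with adjusted p = 0.294 with an estimated correlation. The splicing factor ESRP1 was at 0.02 ± 0.03 TPM and the adhesion gene CDH1 at 0.36 ± 0.42. PODN (chromosome 1, 53062052 to 53085502) was at 97.1 ± 41 TPM, and the hair keratin-associated gene KRTAP1-5 at 61.5 ± 16.5.

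A549 was marked by detoxification genes. Of 20 targets of the oxidative stress factor NRF2, 19 were higher (camera adjusted p = 1.27e-13, and adjusted p = 0.0058 with an estimated correlation). AKR1B10 was at 5508 ± 1557 TPM and ALDH3A1 at 3028 ± 423. AKR1C2 and AKR1C3, of a family of similar genes that can share reads, were at 4545 ± 1085 and 3943 ± 615. Lung markers did not move together: 5 of 12 alveolar and airway genes were higher and 2 lower, or 1 lower without any 1 of the A549 libraries (camera adjusted p = 0.542). The median log2 change was -0.34, and it turned to 0.23 without HepG2. The mean change and the camera direction were positive. The mucin genes MUC5AC and MUC5B were at 105 ± 36.2 and 83 ± 13.3 TPM. CEACAM6 (chromosome 19, 41750977 to 41772208), a cell adhesion gene, was at 1187 ± 50.4 TPM, against 7.46 ± 6.87 in Caco2.

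U251 and U2-OS were weakly matched by the lists of their tissue labels. In U251, 9 of 15 astroglial genes were higher and 2 lower, or 3 when adjusted over the list alone (camera adjusted p = 0.0624). FABP7 was at 125 ± 32.5 TPM and the stem cell factor SOX2 at 39.4 ± 5.75. Of the mesenchymal genes, 18 of 20 were higher in U251 and 1 was lower (adjusted p = 0.0292 with an estimated correlation), with AXL at 418 ± 61.6 TPM. IL13RA2 (chromosome X, 115003975 to 115019977), a decoy receptor for an interleukin, lay above the next line, SK-Mel 24 (11.3 ± 1.4 TPM), by 4.44 on the log2 scale, and EPHA3 was at 62.2 ± 13.6. In U2-OS, 5 of 11 osteoblast genes were higher and 2 lower (camera adjusted p = 0.56), with COL1A1 at 384 ± 222 TPM and COL1A2 at 0.43 ± 0.105.

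U2-OS stood out for cancer-testis genes. Of the 14 tested members, 13 were higher (camera adjusted p = 2.11e-07, and adjusted p = 0.00887 with an estimated correlation), among them MAGEB2 at 121 ± 22.8 TPM, MAGEA4 at 214 ± 33.4 and MAGEA1 at 121 ± 18.7. These families have near-identical copies, so single members are uncertain. So are the enriched genes PAGE2B at 419 ± 21.2 TPM, TUBA3C at 233.9 ± 18.9 and the intronless RPL10L at 52.9 ± 11.5. The hair follicle keratin gene KRT75 was at 146 ± 35.4 TPM. With DESeq2, U2-OS had 188 enriched genes of any type instead of 329, and RPL10L and KRT75 lost their calls.

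The third comparison set the 2 skin lines against each other. SK-Mel 28 was higher in 2666 genes and lower in 2838. Pigment genes were far higher in SK-Mel 28: 16 of 20 melanocyte genes rose and 2 fell (camera adjusted p = 7.27e-10, and adjusted p = 0.00902 with an estimated correlation). The log2 fold change was 11.48 ± 0.97 (SE) for PMEL (13.96 as fitted without SK-Mel 24 replicate 3, which held most of its PMEL counts), 11.44 ± 0.69 for MLANA, 10.31 ± 0.46 for TYR and 4.60 ± 0.25 for MITF, the master regulator of the lineage. MITF was at 240.6 TPM in SK-Mel 28 and 11.8 in SK-Mel 24. MITF, SOX10 and S100B were chosen for this comparison after their values were seen. SOX10, which acts upstream of MITF, was at 245 ± 38.5 TPM in SK-Mel 28 and 252 ± 30.8 in SK-Mel 24 and did not pass the test (log2 fold change 0.08 ± 0.28). S100B was higher in SK-Mel 24 (log2 fold change -2.15 ± 0.31).

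SK-Mel 24 had the higher mesenchymal and inflammatory levels. Relative to it, 12 of 20 mesenchymal genes fell in SK-Mel 28 and 1 rose (camera adjusted p = 2.56e-05), with adjusted p = 0.091 with an estimated correlation. TGFBI went from 1080 ± 62.9 to 0.53 ± 0.35 TPM (log2 fold change -11.9 ± 0.43) and the receptor tyrosine kinase AXL from 192 ± 6.83 to 0.45 ± 0.26 (-9.34 ± 0.53). In the fibroblast list 12 of 20 fell and 2 rose, or 13 fell adjusted over the list alone (camera adjusted p = 0.000171), with adjusted p = 0.23 with an estimated correlation. THY1 was at 29.8 ± 3.76 TPM in SK-Mel 24 and 0.19 ± 0.27 in SK-Mel 28, and FAP at 46.4 ± 3.81 and 0.38 ± 0.33. In the extracellular matrix list 12 of 20 fell, or 13 adjusted over the list alone (camera adjusted p = 1.72e-06), with adjusted p = 0.0925 with an estimated correlation. In the NF-kB inflammatory list 14 of 18 fell and none rose (camera adjusted p = 1.01e-05), with adjusted p = 0.263 with an estimated correlation. The chemokine genes CCL2 and CXCL8 were at 2948 ± 1714 and 1211 ± 1072 TPM in SK-Mel 24 and at 0.11 ± 0.19 and 3.97 ± 1.82 in SK-Mel 28.

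All 8 class II antigen presentation genes were lower in SK-Mel 28 (camera adjusted p = 1.53e-09, and adjusted p = 0.00984 with an estimated correlation). Their median log2 change was -10.49 as fitted and -9.06 with the 4 genes at 0 in SK-Mel 28 set to their bounds. Without MHC region genes the list, then CD74 and CIITA, had adjusted p = 0.0735. CD74, the invariant chain, went from 3265 to 501 TPM (log2 fold change -2.61 ± 0.41) and CIITA, the class II transactivator, from 35.7 to 3.16 (-3.68 ± 0.32). Both were chosen after their values were seen. The MHC region members HLA-DQB1 and HLA-DRB1 were at least 4174-fold and 3630-fold lower, with the same reservation about shared copies.

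On chromosome 9p21, 4 of 7 tested genes were higher in SK-Mel 28 (camera adjusted p = 0.000472, and adjusted p = 0.0252 with an estimated correlation). CDKN2A, which encodes the inhibitor p16, was at 78.9 ± 15.5 TPM in SK-Mel 28 and 0.06 ± 0.1 in SK-Mel 24. Its neighbour CDKN2B was at 19.1 ± 1.18 TPM and at least 703-fold higher than in SK-Mel 24. The adjacent MTAP (chromosome 9, 21802543 to 21937651) was at 57.5 ± 3.15 and 1 ± 0.74 TPM. Its log2 fold change was 6.32 ± 0.27.

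Among the most changed genes, BMP7, a bone morphogenetic protein (chromosome 20, 57168748 to 57266629), and the imprinted gene NDN were at 0 counts in SK-Mel 24 and at least 2098-fold and 1038-fold higher in SK-Mel 28. In the other direction, LRRC17, PTPRN2 and the growth factor PTN were at least 2481-fold, 2736-fold and 841-fold lower in SK-Mel 28. LOXL4, a matrix crosslinking enzyme, went from 911 ± 61.7 to 0.06 ± 0.05 TPM. Testing against a 2-fold change itself left 1695 higher and 1869 lower genes. Per the labels SK-Mel 24 was grown with 15% serum and SK-Mel 28 with 10%, so line and serum cannot be separated here. Library codes in the labels, whose meaning is not stated, lie in separate ranges for these lines, so any batch they mark cannot be separated from the line either.

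**Figure D3:**
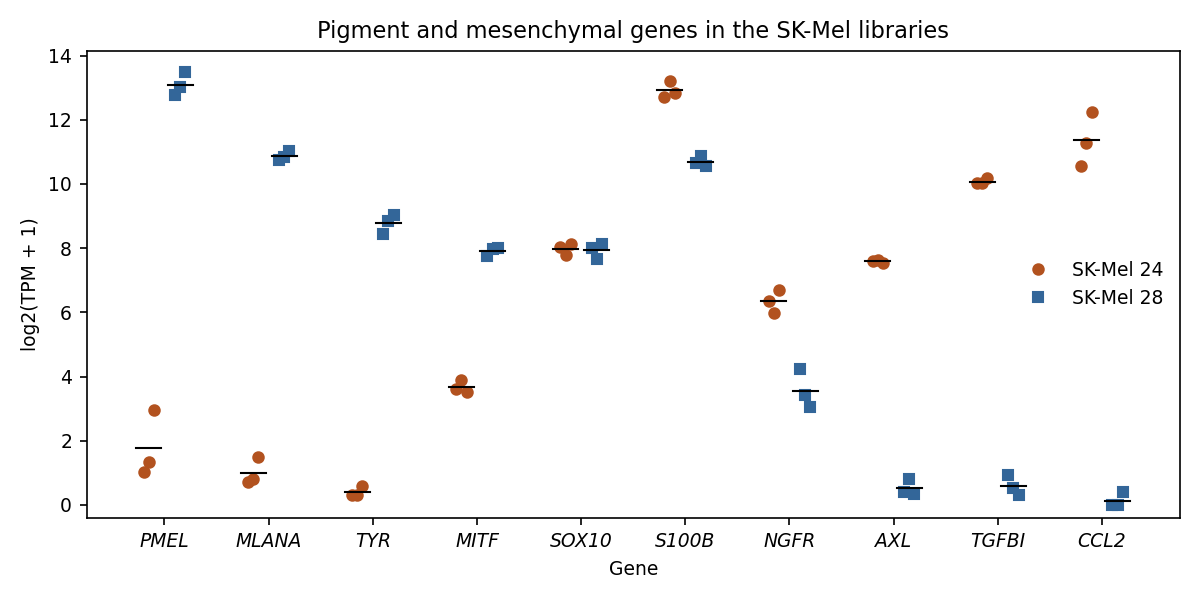
Level of 10 pigment, neural crest, mesenchymal and inflammatory genes as log2(TPM + 1) in the 3 SK-Mel 24 libraries (circles) and the 3 SK-Mel 28 libraries (squares), with bars at the means. PMEL, MLANA, TYR and MITF are higher in every SK-Mel 28 library, AXL, TGFBI and CCL2 in every SK-Mel 24 library, and SOX10 overlaps.

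The fourth comparison set the mean of the skin lines against the mean of the other 7. For this mean, 19 of 20 melanocyte genes were higher and none lower (camera adjusted p = 2.26e-13, and adjusted p = 0.0058 with an estimated correlation). Each skin line on its own was above the mean of the other 8 lines in 11 of the 20, and SK-Mel 28 alone in 9, including TYR (444 ± 89.3 TPM, and 0.33 ± 0.16 in SK-Mel 24). SOX10 (chromosome 22, 37970686 to 37987422) was at 252 and 245 TPM in SK-Mel 24 and SK-Mel 28 and at most 0.05 ± 0.08 in HepG2, the next line (log2 difference of the group means 13.4 ± 0.22). For S100B this difference was 12.65 ± 0.21. MIA, a secreted melanoma protein, was at 1134 ± 190 TPM in SK-Mel 28, the lower of the pair by fitted level, against 6.39 ± 2.72 in U2-OS. The nuclear receptor gene RXRG was at 37.9 ± 1.68 TPM in SK-Mel 28.

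In total 3093 genes were higher and 2186 lower in the skin lines, and 671 lay above and 503 below all 7 other lines in both. Epithelial genes were lower (13 of 20, with 1 higher, adjusted p = 0.0317 with an estimated correlation; 9 were lower in each line on its own), with KRT19 at 0.12 ± 0.11 and 0.25 ± 0.25 TPM and EPCAM at 0.05 ± 0.08 and 0.17 ± 0.16 in SK-Mel 24 and SK-Mel 28. Cancer-testis genes were higher in the mean (11 of 14, adjusted p = 0.0347 with an estimated correlation), but only 5 were higher in each line on its own, and 7 differed by 16-fold or more between the pair. MAGEC2 was at 147 ± 13.6 TPM in SK-Mel 24 and 0.02 ± 0.03 in SK-Mel 28. PRAME was at 98 ± 7.6 and 175 ± 18.7 TPM, and MAGEC1 at 56.9 ± 10.6 and 41.6 ± 5.99. Members of the interferon response list (11 higher, 1 lower of 20, camera adjusted p = 0.0163) lost the call, at adjusted p = 0.581 with an estimated correlation. When both skin lines had to pass against each of the other 7, 139 genes were higher and 38 lower.

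The last comparison asked whether lines used different transcripts of the same gene. Of 11316 eligible genes, 2916 (25.8%) had another dominant transcript in at least 1 of the 36 pairs of lines, and 1010 did without HepG2. Pairs with HepG2 switched in 892 to 1702 genes (12.7% to 24.9%), and pairs of other lines in 48 to 262 (0.58% to 3.09%). Between the SK-Mel lines 61 genes switched. They included MITF, whose transcript MITF-204 held 43.1% of its TPM in SK-Mel 24 and 9.4% in SK-Mel 28, against 11.2% and 49.1% for MITF-203. In FGFR2, a fibroblast growth factor receptor, transcript FGFR2-213 was dominant in the epithelial lines Caco2 (63.7%) and RT4 (50.6%). In U2-OS it was FGFR2-206 (43.1%). Estimates of transcripts that share most of their sequence are less certain than gene totals. The SK-Mel count was 97 without SK-Mel 28 replicate 1. With a library left out, fewer libraries must share the dominant transcript and reach the count minimum. The rule is then looser, so a higher count was likely from the rule itself.

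**Figure D4:**
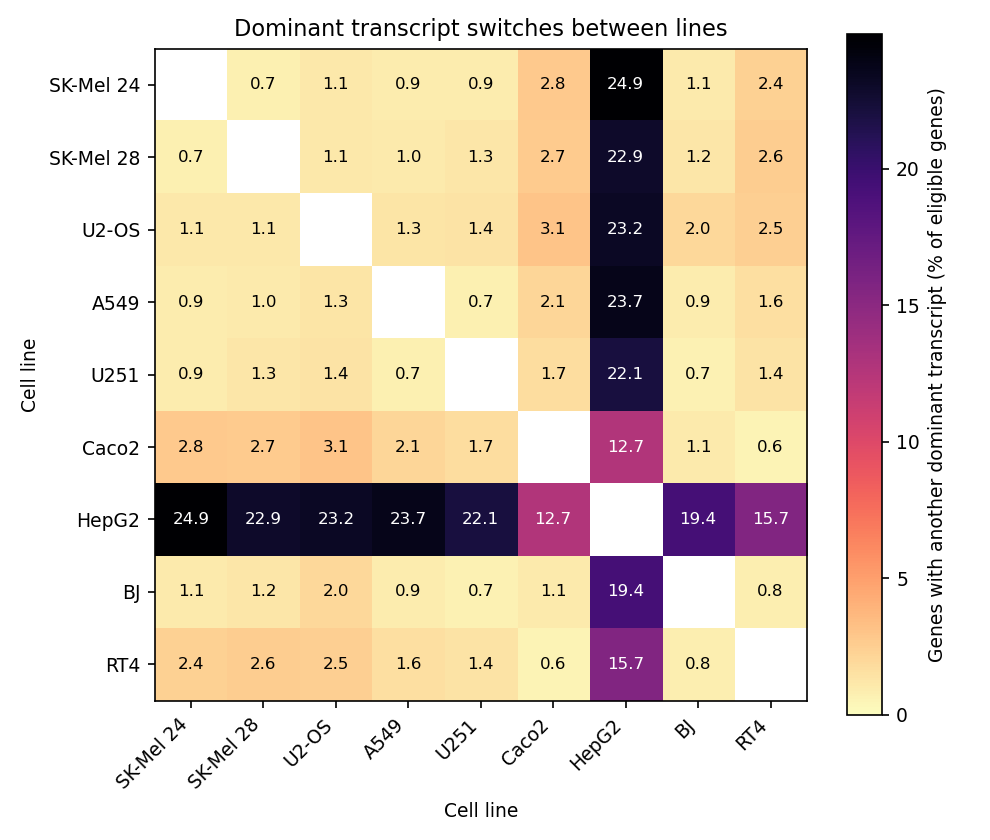
Percent of eligible genes whose dominant transcript differed between each pair of lines, with lines on both axes. Pairs with HepG2 lie between 12.7% and 24.9%, and all other pairs at 3.09% or less.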

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

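The test of shared reads in the MHC region was chosen only after the result was seen, and the test of region-wide silencing was not.

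Transcripts that matched no gene of the annotation were left out of the comparisons, and they carried counts in every library. Their share ranged from 0.745% to 3.065% of the estimated counts of a library, above the 3 counts that an observed 0 allows.

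Among protein-coding genes of the MHC region on chromosome 6 that reached 10 TPM in some line, 17 of 66 (25.8%) were at 0 counts in all 3 libraries of another line. Elsewhere in the genome this held for 858 of 11444 genes (7.50%, Fisher's exact test, two-sided p = 5.82e-06). Silencing of the whole region was looked for as 1 line holding most of these gene and line pairs at 0. The largest share was 16.7%, in SK-Mel 28. A line can hold each of the 17 genes only once, and most were at 0 in more than 1 line. No line could therefore hold most of the pairs, so the test cannot decide on silencing. Of the 17 genes, 11 were at 0 in SK-Mel 28, 10 in U251, 10 in BJ and 1 in RT4. Reads shared with copies of the region that matched no gene here may account for such zeros, and true differences between lines stay open as well. Levels of genes in this region are therefore reported as uncertain.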

How the results depend on the processing

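Fits without HepG2, without mitochondrial genes and without MHC genes were chosen after the data were seen. A summary result with a p-value was kept when its direction and side of the threshold held. Counts have no p-value and were kept within a set fold of the main value, so kept counts can have shifted. Correlations were kept within the SD over pairs of libraries. By these rules 736 values under all alternatives were kept, 25 moved, 6 gained and 5 lost a call, and 1 reversed. Except where stated, the cause was not tested. The astroglial list in U251 (median log2 difference 1.66) passed with DESeq2 size factors (1.60), without the low-count filter (1.62), without HepG2 (1.90) and with fry (1.66). The melanocyte list in SK-Mel 24 lost its call without HepG2 (1.78), with an estimated correlation (1.76) and without replicate 3 (1.18 to 2.00 over left-out replicates), and its lower members numbered 1 without the filter or with length offsets and 1 to 3 with a replicate left out. The alveolar list in A549 reversed in median without HepG2 (-0.34 to 0.23, adjusted p = 0.374) and passed with fry at -0.34, and its lower members numbered 1 with the P number as covariate and 1 with any replicate left out. Lower astroglial members in U251 numbered 1 without HepG2. With fry the osteoblast list passed (0.92). With an estimated correlation the kidney list in RT4 (-3.80) and the epithelial list in BJ (-3.42) lost their calls. Of 440 list tests, 158 passed, 43 with an estimated correlation and 338 with fry, which tests another hypothesis. DESeq2 gave 188 U2-OS enriched genes and 7 lower kidney genes in RT4, and Caco2 had 445 enriched genes without HepG2, as 1 line fewer must be exceeded. Stricter rules gave 1695 and 1869 genes between the SK-Mel lines (glmTreat), and 139 and 38 for skin (14 pairwise tests). SK-Mel transcript switches numbered 111 with a lower count minimum, 24 with a larger share difference and 69 to 97 with a replicate left out. Leaving out a replicate loosens the switch rule, so higher counts were likely. Over all pairs without HepG2, 1010 genes switched. Median replicate correlation was 0.991 with Pearson's coefficient and 0.981 over genes at 1 TPM or more, where the median between lines was 0.737. Another pseudocount leaves ranks as they are, so that alternative was void.

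Of 106 calls of named genes, DESeq2 lost 22 and none reversed; FDCSP also lost its calls without the low-count filter. The P number as covariate lost 4, single left-out libraries lost 6 calls of 3 genes, and size factors, length offsets and the fit without mitochondrial genes lost 1 each, none of a gene named in the text. With the P number as a replicate block in the 6 SK-Mel libraries, 2427 genes were higher and 2670 lower, against 2432 and 2648 without it. Libraries with the same number correlated at 0.096, 0.269 and 0.109 in their deviations, each highest with its own number, which is a hint from the data and not from the design.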

Other observations

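The tests of mitochondrial genes in HepG2 and all 3 tests on SK-Mel 24 were chosen only after the results were seen, and the first test of fibroblast cells was replaced by the one given here.

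HOX genes mark position along the body axis. Genes of the HOXB cluster were low in HepG2 (0 of 9 higher, 5 lower, adjusted p = 0.00902 with an estimated correlation) and in BJ (1 higher, 3 lower, adjusted p = 0.00887 with an estimated correlation). HOXB7 stood at 0.12 ± 0.01 TPM in HepG2 and 0.02 ± 0.03 in BJ, and at 56 ± 2.26 in SK-Mel 24; it was chosen for HepG2 and SK-Mel 24 after its values were seen. All 9 were higher in the mean of the skin lines, 8 of them in each line on its own (adjusted p = 0.009 with an estimated correlation), with HOXB2 at 34.9 ± 2.64 and 15.8 ± 2.6 TPM. High HOXB levels were not particular to the skin lines. The cluster's median log2(mean TPM + 1) was 3.77 in SK-Mel 24 and 2.54 in SK-Mel 28, but also 3.35 in A549 and 2.74 in U2-OS. The low levels in HepG2 (0.014) and BJ (0.024) pull the mean of the other lines down. In BJ, 17 of 20 S-phase genes were lower (camera adjusted p = 3.53e-06), with adjusted p = 0.462 with an estimated correlation. The libraries of this line differed: the median over S-phase genes was 39.1 TPM in replicate 1 and 9.96 and 7.62 in replicates 2 and 3. CDC6 was at 4.96 ± 5.92 TPM, and the median log2 difference of the list was -1.70, or -2.96 without replicate 1. The p53 target CDKN1A was at 622 ± 84.4 TPM (8 of 20 targets higher and 1 lower, adjusted p = 0.0213 with an estimated correlation).

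Of the 16 growth receptor genes, 3 were higher and 8 lower in SK-Mel 28 (camera adjusted p = 0.0169), with adjusted p = 0.0673 with an estimated correlation. In the other 8 lines this list did not pass (camera adjusted p from 0.267 to 0.956), and single members differed. AXL was at 418 ± 61.6 TPM in U251 and 0.21 ± 0.03 in RT4, whereas KIT was at 22 ± 5.84 in RT4 and at 3.34 ± 1.38 or less elsewhere. FGFR4 was at 99.8 ± 20 TPM in Caco2 and 68.6 ± 35.4 in HepG2, and PDGFRB at 144 ± 39.9 in BJ. Among telomere genes, TERT was at 0.02 ± 0.01 TPM in U2-OS and ATRX at 102 ± 14.1. MTAP was at 0.26 ± 0.17 TPM in A549, 0.47 ± 0.22 in RT4 and 1 ± 0.74 in SK-Mel 24, and at 8.84 ± 3.19 or more in the other lines.

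HepG2 had the most line-enriched genes, 657. Its levels had the strongest trend with transcript length of all lines (rank correlation -0.21). A length trend alone is argued against as the whole source, since the count was 694 after each library's trend was removed (next line 366). Without mitochondrial genes the count was 692 (next line 357). TMM factors had already scaled for the mitochondrial share, so this fit cannot decide whether that share matters. The dominant transcript of HepG2 was the shorter one in 78.6% of its 11268 switches (median 1715 against 2472 nucleotides). Fragmented RNA may therefore account for transcript switches in HepG2, although per the labels' protocols the RNA met a stated integrity threshold. A biological difference of the line stays open and untested.

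SK-Mel 24 had low pigment and high mesenchymal levels. Of the fibroblast list, 12 of 20 members were also lower in SK-Mel 28 than in SK-Mel 24, with 2 higher (camera adjusted p = 0.23 with an estimated correlation). Fibroblast cells in the SK-Mel 24 libraries are argued against as the whole source, because the median SK-Mel 24 to BJ ratio was 0.0121 over 18 fibroblast genes and 0.482 over 19 mesenchymal genes. Cells of a line with MTAP are argued against as the main source, though a smaller share of them stays open: MTAP in SK-Mel 24 was at 7.51% of the level in Caco2, the lowest line at 10 TPM or more (12.1% in the highest library), and at 11.3% of that in HepG2. Low depth is argued against by a lowest PMEL count of 8 at a 2867-fold lower mean TPM than in SK-Mel 28 (6960-fold as a ratio of mean TPM without replicate 3, which held 167 of the counts, against 8 and 22). A melanoma cell state with little MITF activity may be a candidate explanation, but it was not tested, as only RNA levels were analysed. The serum difference, a batch behind the library codes and a different line history stay open and untested as well.

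For 3 counts, only the real 1 of 60 assignments of the 27 libraries was as large. The other assignments mix libraries of different lines, and libraries of a line resemble each other most, so lower counts were bound to follow. These counts therefore show no more than that libraries group by line. The real count and the highest other were 16922 and 431 for genes differing across lines, 2424 and 6 for line-enriched genes, and 52491 and 4028 for gene and line pairs. For list tests 1 of 60 assignments was as large too, but the real count was 158 and the highest other 155, so this count says little about the lines. A mixed assignment thus passed 155 of the 440 camera tests with the preset correlation. A pass with the preset correlation alone is therefore weak evidence about a line. For the SK-Mel pair the 10 splits were too few (5504 real, 0 highest other). For skin, 5 of 36 pairs of lines gave as many genes as the 5279 observed, the highest 7034 for Caco2 with HepG2, so chance was not excluded; the 4 higher pairs all contained HepG2.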
